A study of Homo sapiens with 10 samples.

How the data were processed

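Messenger RNA libraries of MCF10A cells were prepared with a KAPA mRNA HyperPrep kit from TRIzol extracts, per the labels. The 10 libraries fall into 5 groups of 2: 400 Pa, 1 kPa, 6 kPa and 60 kPa gels at 5 mM glucose, and 400 Pa gels at 25 mM glucose. The labels name 2 biological replicates per condition, each a pool of 4 gel cultures kept for 24 h. The concentration of 25 mM comes from the description of the series, and the sample labels say high glucose. The labels give gel recipes for 400 Pa, 6 kPa and 60 kPa, and the recipe for 1 kPa is not given in the sources used here. The table columns carry a letter and a group but no replicate number, so libraries are named below by group and depth. The command in the header of the FPKM table reads the deeper 1 kPa library from a directory whose name does not state a gel, and its group was taken from the column heading.

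Reads were aligned to hg19 with STAR and counted with HOMER, per the submitters' processing notes, which give no versions. Tags in exons were counted for 1 transcript per gene with HOMER's analyzeRepeats.pl, per the file headers, in a command that sets no strand option. The log2 values of each of 2 comparison tables were made by the authors from such tags with HOMER's getDiffExpression.pl, per the file headers, and the submitters' notes name DESeq2. These deposited log2 values are variance-stabilised and normalised within their own 4 libraries, and genes without a tag in those libraries are written as 0. The log2 fold change, p-value and adjusted p-value columns were computed by the authors in the same step, per the file headers, with the second group over 400 Pa. The FPKM values of all 10 libraries were made by the authors with the -rpkm option of analyzeRepeats.pl, per the file headers, and are rounded to 3 decimals. Each table lists 27942 genes, of which 8939 had no tag in the 4 libraries of the stiffness table. Other deposited tables hold genes of the full tables selected by fold change and were not used here.

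Whole reads were recovered from FPKM, exon length and library total, with totals from the table headers for 6 libraries and recovered from the values for those of 1 and 6 kPa. In every library 100% of the tested values, those whose rounding error was under 0.1 reads, lay within 0.12 of a whole number (largest distance 0.096). Mapped reads (M, in units of 1e6) were 28.61 and 12.95 M at 400 Pa, 11.3 and 5.75 M at 1 kPa, 4.97 and 2.98 M at 6 kPa, 7.14 and 5.86 M at 60 kPa and 7.09 and 6.34 M at 25 mM. Exon reads made up 62.0 to 71.7% of them, and the 10 highest genes took 3.8 to 5.4% of exon reads. Pearson correlations of the libraries of a group were 0.992 (400 Pa), 0.980 (1 kPa), 0.955 (6 kPa), 0.981 (60 kPa) and 0.979 (25 mM). The spread between them was 1.95 to 7.34 times that of Poisson counts, highest at 6 kPa.

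For stiffness (60 kPa against 400 Pa) and glucose (25 mM against 5 mM on 400 Pa), the deposited log2 values of 4 libraries were fitted with limma 3.58.1 in R 4.3.3 (eBayes with trend), over genes not written as 0 and with a mean of at least the log2 of 10. P-values were adjusted with the Benjamini-Hochberg method and called under 0.05. These fits have 2 residual degrees of freedom, and limma's prior degrees of freedom were 46.1 and 182.6. Their standard errors and p-values therefore rest mostly on the trend across genes, and little on the spread of each gene. The plan made before the data were examined foresaw a count test if the tables held counts, and limma if they held normalised values; the tables hold log2 values, so limma was used. The values had been stabilised across genes before the test, so standard errors may be too small for genes with few reads.

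For the other comparisons limma was fitted to log2(FPKM + 1) of genes with a mean of at least 0.5 FPKM. All 10 libraries in 5 groups shared 1 estimate of the spread (5 residual degrees of freedom), and a slope per 10-fold of stiffness in Pa was fitted to the 8 libraries at 5 mM. The direct contrast of 60 kPa with 25 mM glucose was planned as part of the comparison of responses, and its count of calls was added later. That comparison used correlation, covariance and overlap across genes, with 100 simulations of unchanged groups against the same 400 Pa libraries.

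The 37 gene lists were fixed before the data were examined, 3 of them for RNA quality and 3 for other cell types. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with at least 3 measured members. Camera with an estimated correlation and fry were run as alternatives. Of the list genes, 3 noncoding RNAs matched no gene of the tables. Named genes follow a rule fixed before the data were examined. It takes the 6 largest rises and 6 largest falls past the test with a mean of at least 5 FPKM, and up to 3 members past the test with the highest expression in each list, or 2 measured members where none passed. It adds a list of genes fixed by name, and the 5 steepest slopes in each direction. Some genes that the rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen. PPARGC1A and ANKRD1, fixed by name, were below the filter.

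After the libraries were seen to differ along GC content, a correction was added. In each library the deviation from the gene mean was fitted on transcript GC content (GENCODE 29, known for 98.7% of genes) with a symmetric loess and subtracted, before the same tests. Also added after seeing the data were limma-voom fits on the recovered reads with TMM, median-of-ratios and upper-quartile scaling, a fit of 3 groups, and a fit after thinning to equal depth. TMM factors were computed in R from their definition. Settings foreseen from the start were pseudocounts, filters, scaling, a 2-fold minimum, the authors' adjusted p and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.

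The fits were tested on simulated data with 200 genes changed, 50 at each fold. For the deposited values these were log2 values with normal noise of the fitted spread. For FPKM and recovered reads they were reads drawn with a dispersion of 0.01 and no GC trend. For stiffness (12712 genes) limma on log2 values found 72% of 1.25-fold and 100% of larger changes and called 10 of 12512 unchanged genes. For glucose (12821 genes) it found 96% of 1.25-fold and 100% of larger changes and called 17 of 12621. On simulated reads limma-voom for stiffness (13013 genes) found 4% of 1.25-fold, 30% of 1.5-fold, 78% of 2-fold and 98% of 4-fold changes and called 2 of 12813 unchanged genes. On simulated log2(FPKM + 1), 60 kPa against 400 Pa (12835 genes) gave 92% of 4-fold, 62% of 2-fold and 6% of 1.5-fold changes. On log2(FPKM + 1), 1 kPa against 400 Pa (12827 genes) gave 88% of 4-fold, 40% of 2-fold and 2% of 1.5-fold changes, and the slope (12818 genes) gave 96%, 58% and 10%. With a list shifted by 0.2 on the log2 scale (12720 genes), camera called that list and 0 others, whereas camera with an estimated correlation called 0 lists, so its p-values can miss a real shift here.

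RBMXL2 and TIGD6 may take reads of other genes. The same holds for genes with processed pseudogenes or close copies, such as FTH1, FTL, GAPDH, ribosomal protein genes, KRT6A, KRT16, KRT17, HSPA1A and the actins and tubulins.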

Results

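Messenger RNA was sequenced from MCF10A cells, a non-tumorigenic human mammary epithelial line, after 24 h on fibronectin-coated polyacrylamide gels. Gels of 400 Pa, 1 kPa, 6 kPa and 60 kPa were compared at 5 mM glucose, and the softest gel was also used at 25 mM glucose. Each of the 5 groups had 2 libraries, which the labels call biological replicates, and each library was a pool of 4 gel cultures. The 10 libraries held between 2.98 and 28.61 M mapped reads, and their exon reads ranged from 1.97 M (a 6 kPa library) to 18.4 M (a 400 Pa library). Between 14467 and 17989 genes had at least 1 read in a library. The 400 Pa libraries at 5 mM glucose were the deepest, at 28.61 and 12.95 M mapped reads, so low genes were measured less precisely in the other groups. Values are given as FPKM ± SD (n = 2), and log2 fold changes with their standard error. The log2 fold changes of the main comparisons are on the deposited variance-stabilised scale, which shrinks those of genes with few reads.

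The libraries also differed along the GC content of the transcripts. Across genes, which are not independent replicates, the deviation of a library from the gene means had a Spearman rho with GC of 0.61 and 0.66 in the 400 Pa libraries at 5 mM, 0.62 and 0.59 at 1 kPa, and 0.62 in the deeper 6 kPa library. The other 6 kPa library had a rho of -0.31, the 60 kPa libraries had -0.60 and -0.57, and the 25 mM libraries had -0.64 and -0.66. The log2 fold changes of both main comparisons followed GC content (rho across genes of -0.74 for stiffness and -0.78 for glucose). A correction for GC content was therefore added after the data were seen. For most results, though not for every list at 1 and 6 kPa or in the direct contrast, counts or p-values after it are given beside those without it.

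**Figure D1:**
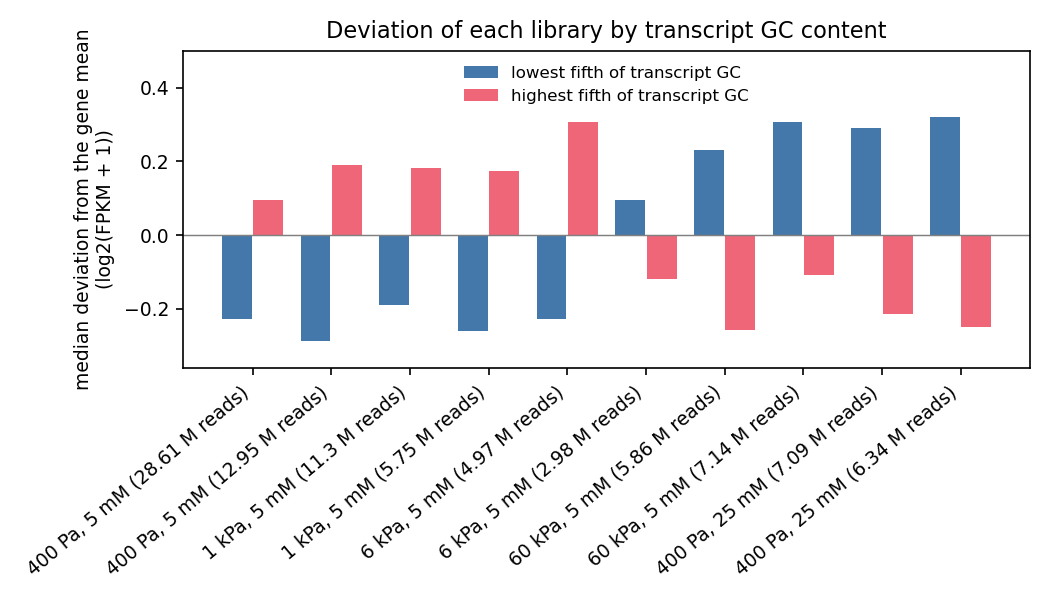
Median deviation of each library from the gene means, in log2(FPKM + 1), over the genes with a transcript GC content under 41.4% (blue) and over 58.6% (red); the horizontal axis lists the 10 libraries with their group and mapped reads in M. The deeper 6 kPa library lies at -0.23 and 0.31, on the side of the softer gels, and the other 6 kPa library at 0.10 and -0.12.

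The design asks how mammary epithelial cells respond to a soft-to-stiff change of their substrate. On 60 kPa gels, mRNAs of cell division were higher than on 400 Pa gels, and mRNAs of cornification, of luminal and basal markers, of NRF2 targets and of ATF4 targets were lower. These calls used a preset correlation between genes, and with an estimated correlation none passed (adjusted p = 0.222 to 0.278). The steepest fall was that of KRT15, a keratin of basal epithelial cells, from 201 ± 11.4 FPKM on 400 Pa gels to 19.7 ± 2.6 on 60 kPa gels. Its log2 fold change was -3.02 ± 0.06 (limma with Benjamini-Hochberg adjustment, adjusted p = 2.47e-39), and the authors' deposited table gave -3.43. On log2(FPKM + 1) limma gave a change of -3.29 with an adjusted p of 2.41e-06. KRT15 was counted on transcript NM_002275, on the minus strand of chromosome 17 from 39669997 to 39675270 in hg19. ALDH3A1, an aldehyde dehydrogenase, fell from 215 ± 9.99 to 48.8 ± 4.3 FPKM, with a log2 fold change of -2.04 ± 0.06. Other large falls were those of the keratin KRT16 (-1.78 ± 0.07), the ion transport regulator FXYD3 (-1.62 ± 0.07), the monoamine oxidase MAOA (-1.61 ± 0.07) and the sodium channel subunit SCNN1B (-1.60 ± 0.07). The largest rises on the stabilised scale were smaller: DEK, a chromatin protein, went from 34.1 ± 2.43 to 98.0 ± 8.34 FPKM, a log2 fold change of 1.30 ± 0.06. HMMR and DLGAP5, of the mitotic spindle, rose by 1.28 ± 0.07 each, the condensin subunits SMC2 and SMC4 by 1.26 ± 0.06 and 1.23 ± 0.06, and the kinetochore protein KNL1 by 1.24 ± 0.07.

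**Figure D2:**
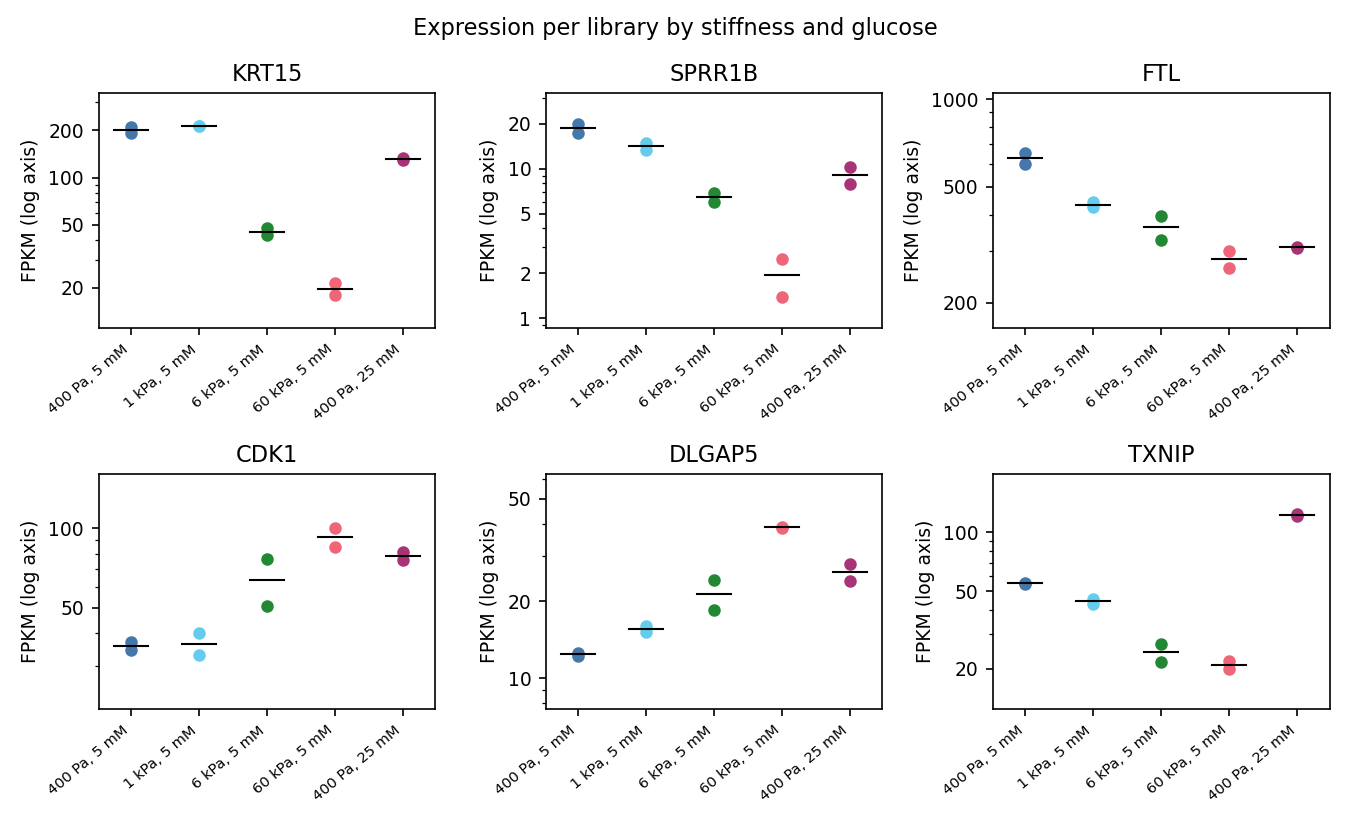
FPKM of 6 genes (log axes) in each of the 10 libraries by group; points are libraries and black bars are group means. KRT15 averaged 201, 213, 45.4 and 19.7 FPKM from 400 Pa to 60 kPa, whereas CDK1 averaged 35.7, 36.6, 63.5 and 92.4, and TXNIP averaged 54.7 FPKM at 5 mM and 122 at 25 mM glucose on 400 Pa.

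Cell cycle genes of S and G2/M phase rose as a group on the stiff gel. Of 27 measured members, 21 rose and 0 fell (adjusted over the list alone, 21 rose and 1, MCM5, named for that reason, fell), and limma's camera test gave an adjusted p of 1.69e-10, with adjusted p = 0.222 with an estimated correlation. CCNB1, the mitotic cyclin, rose by 0.65 ± 0.05, PCNA, the replication clamp, by 0.46 ± 0.06 and the ubiquitin-conjugating enzyme UBE2C by 0.18 ± 0.06. After GC correction 23 members of the list rose and 0 fell. Heat shock and chaperone genes rose more often than they fell, 12 against 3 of 20 (camera adjusted p = 0.00206; adjusted p = 0.49 with an estimated correlation), and 11 against 3 after GC correction. HSP90AA1 rose by 0.90 ± 0.03, HSP90AB1 by 0.18 ± 0.03 and HSPA8 by 0.08 ± 0.03. DNAJB1, HSPB1 and CRYAB fell, with log2 fold changes of -0.14, -1.17 and -0.14, of which HSPB1 and CRYAB were named after their values were seen (CRYAB was at -1.17 and not called on log2(FPKM + 1)). HSPA1A was at 0.01 ± 0.07, and the heat shock factor HSF1 fell by 0.48 ± 0.07. With GC correction HSPA8 (0.03 ± 0.02, adjusted p = 0.31) and DNAJB1 (-0.05 ± 0.05, adjusted p = 0.438) lost their calls, and HSPA1A gained one (0.21 ± 0.07, adjusted p = 0.0122).

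Markers of epithelial differentiation fell. In the keratinocyte cornification list 13 of 16 members fell and 0 rose (14 fell adjusted over the list alone; camera adjusted p = 2.4e-06; adjusted p = 0.222 with an estimated correlation). After GC correction 11 fell and 1 rose. S100P fell by 1.37 ± 0.08 (-2.40 on log2(FPKM + 1)), the suprabasal keratin KRT10 by 1.10 ± 0.07 and S100A9 by 0.36 ± 0.08. Of the luminal mammary markers 7 of 10 fell and 0 rose (camera adjusted p = 5.43e-06; adjusted p = 0.222 with an estimated correlation). After GC correction 7 fell again. Among them were MUC1 at -1.31 ± 0.06, KRT7 at -0.42 ± 0.03 and KRT18 at -0.42 ± 0.05. Basal and myoepithelial markers fell too, 9 of 13 against 2 that rose (camera adjusted p = 5.16e-05; adjusted p = 0.278 with an estimated correlation), 10 against 2 after GC correction. KRT17 fell by 0.97 ± 0.04, KRT14 by 0.46 ± 0.05, KRT5 by 0.42 ± 0.02 and KRT6A by 0.23 ± 0.03. CAV1 (0.32) and EGFR (0.15), named after their values were seen, rose. For epithelial junctions the count was 8 down and 3 up of 17 (camera adjusted p = 0.00992; adjusted p = 0.278 with an estimated correlation; 8 and 2 after GC correction). JUP was at -0.91 ± 0.05, PKP3 at -0.42 ± 0.06 and CTNNB1 at 0.24 ± 0.05.

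Genes of antioxidant defence and of the integrated stress response were lower on 60 kPa. NRF2 targets fell in 15 of 20 cases and rose in 3 (camera adjusted p = 5.02e-07; adjusted p = 0.222 with an estimated correlation), and 15 fell and 0 rose after GC correction. The ferritin chains FTH1 and FTL, which store iron, fell by 1.05 ± 0.03 and 1.18 ± 0.05, HMOX1, which degrades haem, by 0.75 ± 0.08 (-1.64 on log2(FPKM + 1)) and TXNRD1 by 0.29 ± 0.05. TXN rose by 0.22 ± 0.05, a change of 0.05 ± 0.05 after GC correction. SLC7A11, the cystine transporter, rose by 0.21 ± 0.06 and turned to -0.18 ± 0.06 after GC correction, past the test in both. Superoxide, peroxide and glutathione enzymes fell in 15 of 20 cases and rose in 3 (camera adjusted p = 5.46e-05; adjusted p = 0.222 with an estimated correlation; 12 and 2 after GC correction). SOD2 was at -0.72 ± 0.06, GSTP1 at -0.74 ± 0.04, PRDX5 at -0.57 ± 0.06 and PRDX6 at -0.29 ± 0.04. ATF4 targets fell in 16 of 20 cases and rose in 1, SLC7A11 (camera adjusted p = 8.17e-09; adjusted p = 0.222 with an estimated correlation), and in 17 after GC correction. The amino acid transporter subunits SLC3A2 and SLC7A5 fell by 0.62 ± 0.05 and 0.54 ± 0.03, DDIT4 by 0.45 ± 0.05 and ATF4 itself by 0.28 ± 0.05. ATF5 was at -0.21 ± 0.07 without and -0.01 ± 0.07 with GC correction.

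Lists of ribosomal, respiratory, glycolytic and pentose phosphate genes were lower on 60 kPa. Cytosolic ribosomal protein genes, which were also listed as a sign of RNA quality, fell in 29 of 32 cases and rose in 0 (camera adjusted p = 9e-19; adjusted p = 0.344 with an estimated correlation; 30 after GC correction). RPL8 was at -0.51 ± 0.03, RPS14 at -0.34 ± 0.04 and RPS6 at -0.25 ± 0.03. Respiratory complexes II to V fell in 21 and rose in 2 of 38 members (camera adjusted p = 6.19e-06; adjusted p = 0.278 with an estimated correlation; 28 and 0 after GC correction). ATP5F1B was at -0.43 ± 0.04, COX4I1 at -0.40 ± 0.05 and ATP5MF at -0.35 ± 0.06. From 400 Pa to 60 kPa ATP5F1B averaged 512, 424, 423 and 402 FPKM. Complex I had 17 down and 5 up of 37 (18 and 5 adjusted over the list alone; camera adjusted p = 0.00405; adjusted p = 0.563 with an estimated correlation; 15 and 2 after GC correction), with NDUFA13 at -0.42 ± 0.06. Glycolysis and glucose uptake genes fell in 13 and rose in 3 of 21 (camera adjusted p = 4.96e-05; adjusted p = 0.222 with an estimated correlation; 12 and 2 after GC correction). GAPDH was at -0.56 ± 0.02, ENO1 at -0.25 ± 0.03 and PKM at -0.25 ± 0.03. From 400 Pa to 60 kPa PKM averaged 957, 803, 903 and 864 FPKM and ENO1 1699, 1449, 1609 and 1522. Both were thus lowest at 1 kPa among the gels at 5 mM. GAPDH averaged 3132, 2574, 2582 and 2252.5, and TKT, given below, 478, 399, 339 and 273, so these fell further by 60 kPa. At 1 kPa against 400 Pa 0 genes were called singly. Pentose phosphate and serine pathway genes fell in 8 and rose in 4 of 15 (camera adjusted p = 0.00774; adjusted p = 0.278 with an estimated correlation; 8 and 2 after GC correction), and TKT fell by 0.87 ± 0.04.

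Adhesion and cytoskeletal genes did not move one way. SRF and MRTF targets fell in 11 and rose in 2 of 19 (13 and 2 adjusted over the list alone; camera adjusted p = 0.00126; adjusted p = 0.278 with an estimated correlation). After GC correction 7 fell, 3 rose and the camera adjusted p was 0.232. ACTG1 was at -0.36 ± 0.03, FLNA at -0.28 ± 0.03 and ACTB at -0.16 ± 0.02. With GC correction FLNA (-0.06 ± 0.02, adjusted p = 0.0508) and ACTB (-0.03 ± 0.02, adjusted p = 0.103) lost their calls. YAP/TAZ-TEAD targets split into 5 up and 6 down of 21 (camera adjusted p = 0.756; median 0.00, mean -0.04). CTGF and CYR61, secreted proteins often used as readouts of YAP, fell by 0.60 ± 0.08 and 0.36 ± 0.07, ASAP1 rose by 0.43 ± 0.06, and ANKRD1 was below the expression filter. Integrins and focal adhesion genes had 11 up and 8 down of 23 (camera adjusted p = 0.51), with ITGB1 at 0.70 ± 0.05 and ITGB4 at -0.79 ± 0.04. Extracellular matrix genes had 4 up and 4 down of 23 (3 and 4 adjusted over the list alone; camera adjusted p = 0.793; median 0.01, mean -0.01), and FN1 was at 0.00 ± 0.05. NF-kB cytokine genes fell in 6 of 13 cases and rose in 0 (camera adjusted p = 0.0478; adjusted p = 0.632 with an estimated correlation; 9 after GC correction), with NFKBIA at -0.53 ± 0.06. After GC correction YAP targets had 3 up and 4 down, integrins 9 and 5 and matrix genes 8 and 5.

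The other lists did not pass camera on 60 kPa. Mitochondrial protein quality control had 6 up and 7 down of 18 (adjusted p = 0.793; median -0.08, mean 0.04), with HSPD1 at 0.52 ± 0.04, YME1L1 at 0.47 ± 0.06 and PHB2 at -0.44 ± 0.05. Mitochondrial fission, fusion and cristae genes had 7 up and 3 down of 16 (adjusted p = 0.306), including DNM1L, the fission GTPase, at 0.64 ± 0.07. TCA cycle enzymes had 6 up and 9 down of 20 (adjusted p = 0.306) and MDH2 fell by 0.46 ± 0.05. MondoA and ChREBP targets had 0 up and 2 down of 9 (adjusted p = 0.15), and these were TXNIP (-1.25 ± 0.06), an inhibitor of glucose uptake, and G6PC3 (-0.52 ± 0.07). ARRDC4 was at -0.03 ± 0.06, and passed the test at -0.18 ± 0.06 with GC correction. Cholesterol synthesis had 9 up and 9 down of 22 (10 down adjusted over the list alone; adjusted p = 0.565; median -0.07, mean 0.09), fatty acid synthesis 4 and 5 of 14 (adjusted p = 0.835; median 0.03, mean 0.00, test downward), peroxisome genes 6 and 10 of 26 (adjusted p = 0.579) and acid and ion exchange 3 and 6 of 12 (7 down adjusted over the list alone; adjusted p = 0.237). FASN fell by 0.50 ± 0.04. The unfolded protein response had 6 up and 5 down of 16 (adjusted p = 0.579), the hypoxia response 2 and 5 of 17 (adjusted p = 0.75), p53 targets 4 and 7 of 18 (5 and 8 adjusted over the list alone; adjusted p = 0.336), interferon genes 2 and 3 of 15 (adjusted p = 0.75) and mesenchymal markers 3 and 2 of 14 (adjusted p = 0.987; median -0.01, mean 0.03, test downward). With GC correction these lists did not pass either. Their counts up and down were then 5 and 3 for mitochondrial quality control, 3 and 1 for fission and fusion, 2 and 7 for the TCA cycle, 1 and 3 for MondoA targets, 5 and 1 for cholesterol synthesis and 3 and 4 for fatty acid synthesis. They were 2 and 7 for peroxisome genes, 3 and 4 for acid and ion exchange, 4 and 2 for the unfolded protein response, 3 and 7 for hypoxia, 3 and 7 for p53 targets, 3 and 7 for interferon genes and 4 and 4 for mesenchymal markers.

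Lists for RNA quality and other cell types were read the same way. Of the RNA quality lists, ribosomal protein genes fell, as given above, so a difference in RNA quality is not excluded by these lists. Replication-dependent histones had 0 up and 4 down of 7 (camera adjusted p = 0.211), and nuclear-retained noncoding RNAs 2 up and 3 down of 10 (3 and 3 adjusted over the list alone; adjusted p = 0.373; median 0.02, mean -0.09), with MALAT1 at -0.26 ± 0.03. Leukocyte and macrophage markers fell in 4 of 4 cases (adjusted p = 0.0368; adjusted p = 0.469 with an estimated correlation), with CD14 at -0.62 ± 0.08 (-1.52 on log2(FPKM + 1)), from 8.72 ± 0.56 FPKM on 400 Pa to 2.60 ± 1.78 on 60 kPa. After GC correction 3 fell and the list's adjusted p was 0.109. Fibroblast markers had 2 up and 2 down of 5 (adjusted p = 0.51) and endothelial markers 0 up and 1, KDR, down of 3 (adjusted p = 0.756; median 0.01, mean -0.04). KDR had 5 and 12 reads in the 60 kPa libraries, against 100 and 37 in those of 400 Pa at 5 mM. After GC correction histones had 1 up and 2 down, nuclear-retained RNAs 3 and 4, fibroblast markers 1 and 2 and endothelial markers 1 and 1. Except where given, counts adjusted over the list alone equalled those over all genes.

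Of 12720 genes tested on the deposited log2 values, 3382 rose and 3207 fell, 6589 in all, of which 23 rose and 32 fell at least 2-fold on this scale, against 149 and 130 on log2(FPKM + 1). With GC correction 2515 rose and 2447 fell, and 3085 genes were called in the same direction in both fits. In simulated data with the observed GC trend and 200 changed genes, 50.8% of the 12513 unchanged genes were called without the correction and 10 of 12394 with it. The correction fits the same kind of curve that was added, so the second count does not test it on real data. The count was 4365 without the shallower 400 Pa library and 2722 on log2(FPKM + 1), where 1934 rose and 788 fell, or 1499 and 1376 after TMM centring. Among the genes named above, the calls of UBE2C, HSP90AB1, HSPA8, DNAJB1, CRYAB, KRT7, KRT18, KRT6A, EGFR, PKP3, CTNNB1, TXNRD1, TXN, SLC7A11, PRDX6, ATF4, SLC7A5 and ATF5 ended on log2(FPKM + 1). So did those of RPS14, RPS6, ATP5MF, ENO1, PKM, ACTG1, FLNA, ACTB, CYR61, FASN and MALAT1. GC correction moved the log2 fold changes of S100A9, HSF1, KRT5, KRT6A, KRT7, KRT14, KRT18, CAV1, PKP3, CTNNB1, PRDX5, SLC7A5, DDIT4 and RPL8 more than 1.5 times toward 0. The same held for COX4I1, NDUFA13, GAPDH, ENO1, PKM, ACTG1, ITGB1, HSPD1, YME1L1, PHB2, DNM1L, G6PC3 and FASN. It moved RPS6 (-0.42) and MALAT1 (-0.50) away from 0. Without the deeper or without the shallower 400 Pa library UBE2C, HSPA8, DNAJB1, CRYAB, EGFR, SLC7A11, ATF5 and KDR were no longer called. By the authors' adjusted p UBE2C, DNAJB1, CRYAB, ATF5, KDR and CXCL8 were not called. On log2(FPKM + 1) camera gave an adjusted p of 0.0509 for pentose phosphate genes, 0.0523 for epithelial junctions and 0.0258 for histones.

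The intermediate gels show where along the series the changes appear. Between 400 Pa and 1 kPa few differences could be called, and KRT15 averaged 201 ± 11.4 and 213 ± 0.95 FPKM. By 6 kPa it had fallen to 45.4 ± 3.12 FPKM, a log2(FPKM + 1) change of -2.12 from 400 Pa (limma with Benjamini-Hochberg adjustment, adjusted p = 0.000117). SPRR1B, a cornified envelope protein, went from 18.6 ± 1.86 FPKM at 400 Pa to 14.1 ± 1.2, 6.44 ± 0.62 and 1.95 ± 0.79 at 1, 6 and 60 kPa. ATF3, a stress-induced transcription factor, showed its fall between 6 kPa (7.35 ± 1.48 FPKM) and 60 kPa (0.45 ± 0.12), a change of -2.52 (adjusted p = 0.000366). In the 60 kPa libraries ATF3 had 6 and 5 reads and SPRR1B 5 and 11, against 192 and 282 for KRT15, so their changes are less precise. Fitted against stiffness in Pa over the 8 libraries at 5 mM, the steepest falls per 10-fold of stiffness were those of KRT15 (-1.67 ± 0.14), SPRR1B (-1.29 ± 0.08), ATF3 (-1.25 ± 0.20), KRT16 (-1.07 ± 0.11) and the water and glycerol channel AQP3 (-1.02 ± 0.10). The steepest rises were those of SGO2 (0.76 ± 0.09), TTK (0.73 ± 0.07), DLGAP5 (0.71 ± 0.06), NUF2 (0.68 ± 0.06) and CDK1 (0.66 ± 0.08), all of mitosis, with limma adjusted p-values from 0.000491 to 0.00145. With GC correction these rises were 0.43, 0.44, 0.46, 0.40 and 0.36, with adjusted p-values up to 0.00517. Without the 60 kPa libraries the slopes of KRT15, ATF3, KRT16 and these 5 genes were not called.

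Along the slope the cornification list fell in 11 of 18 members and rose in 0 (camera adjusted p = 3.3e-09; adjusted p = 0.0151 with an estimated correlation), and 11 fell with GC correction. Cell cycle genes rose in 20 of 27 members (camera adjusted p = 1.05e-08; adjusted p = 0.461 with an estimated correlation) and ATF4 targets fell in 13 of 19 (camera adjusted p = 5.87e-08; adjusted p = 0.274 with an estimated correlation), against 17 and 8 with GC correction. At 6 kPa against 400 Pa the median change of the cornification list was already -0.68 (camera adjusted p = 5.11e-09; adjusted p = 0.0395 with an estimated correlation) and that of the cell cycle list 0.29 (camera adjusted p = 6.91e-11; adjusted p = 0.313 with an estimated correlation). These medians, without GC correction, average unlike libraries, since the 6 kPa libraries had a rho with GC of 0.62 and -0.31. At 1 kPa the NRF2 list stood at a median of -0.32 (camera adjusted p = 6.76e-15; adjusted p = 0.159 with an estimated correlation) and ribosomal protein genes at -0.19 (camera adjusted p = 8.71e-11; adjusted p = 0.298 with an estimated correlation), with 0 of their members called singly. Across genes the 400 Pa libraries had a rho with transcript length of -0.27 and -0.27, and the 1 kPa libraries of -0.09 and -0.08, a difference that also runs between short and long genes.

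**Figure D3:**
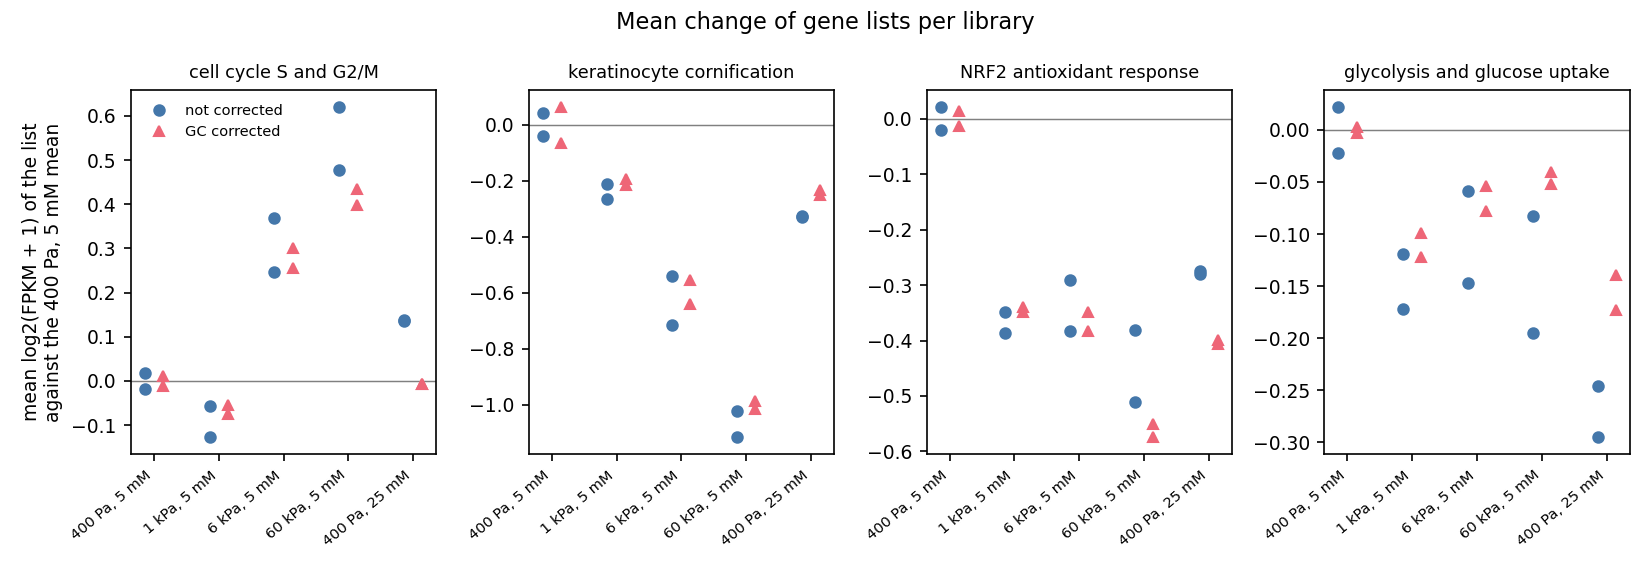
Mean of 4 gene lists in each of the 10 libraries, in log2(FPKM + 1) against the mean of the 400 Pa libraries at 5 mM, without (circles) and with (triangles) GC correction; the horizontal axis gives stiffness and glucose. Cell cycle genes lie at 0.48 and 0.62 in the 60 kPa libraries, or 0.40 and 0.43 with GC correction, and cornification genes at -1.12 and -1.02.

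Over the series 2146 of 12794 genes rose and 851 fell with stiffness in limma's fit, 2997 in all, or 1565 and 1423 after TMM centring. The count was 1058 with GC correction, 14 without the 60 kPa libraries and 983 without the 400 Pa libraries, and leaving out 1 library gave 1639 (the shallower 400 Pa library), 1110 (the shallower 60 kPa library) and 868 (the deeper 60 kPa library). For 1 kPa against 400 Pa limma called 0 of 12820 genes, with 776 at an unadjusted p under 0.05. Other settings called 4 (no filter) and 5 (GC correction), and 6 without the deeper 1 kPa library, 2 without the other and 2 without the deeper 25 mM library. In simulated data for this comparison 88% of 4-fold changes were found, and 40% of 2-fold changes. Those reads were drawn with a dispersion of 0.01 and no GC trend. The share found in the real data may therefore be lower.

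For 6 kPa against 400 Pa 7 genes rose and 38 fell, 45 in all. Leaving out 1 library gave 1777 calls without the deeper 6 kPa library and 89 without the other, 2 without either 400 Pa library, 14 without either 1 kPa library, 23 without either 60 kPa library and 28 without either 25 mM library. Those 6 kPa libraries, which share their treatment, differed from each other along GC content (rho across genes of -0.60) and had the lowest replicate correlation, 0.955, against 0.979 to 0.992 in the other groups. From 1 to 6 kPa 3 genes rose and 22 fell. That count of 25 became 1725 and 40 without the deeper and the shallower 6 kPa library, 2 and 1 without the deeper and the shallower 400 Pa library, 9 and 8 without those of 1 kPa, 1 without either 60 kPa library and 11 without either 25 mM library. From 6 to 60 kPa 7 rose and 19 fell. That count of 26 became 4034 without the shallower 6 kPa library, 2 without either 400 Pa library, 17 without either 1 kPa library, 7 without either 60 kPa library and 16 without either 25 mM library. For 60 kPa against 400 Pa in this table the 2722 calls became 598 and 151 without the deeper and the shallower 400 Pa library, 4501 and 4503 without those of 6 kPa, and 782 and 1083 without those of 60 kPa.

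The glucose comparison asks what 25 mM glucose does to cells on the soft gel. TXNIP, whose transcription rises with intracellular glucose metabolites, rose from 54.7 ± 0.34 to 122 ± 1.87 FPKM. Its log2 fold change was 0.99 ± 0.05 (limma with Benjamini-Hochberg adjustment, adjusted p = 3.57e-44), and the authors' deposited table gave 1.06. That rise was the largest on the stabilised scale among genes with a mean of at least 5 FPKM. On log2(FPKM + 1) CXCL8, given below, rose more. TXNIP was counted on NM_006472, on the plus strand of chromosome 1 from 145438438 to 145442644 in hg19. Lists of glycolytic, ribosomal, antioxidant and basal marker mRNAs were lower at a preset correlation between genes, and none passed with an estimated correlation (adjusted p = 0.561 for each). KRT16 fell by 1.17 ± 0.07, ALDH3A1 by 1.14 ± 0.05, FTL by 1.07 ± 0.04 and KRT17 by 0.93 ± 0.03. RBMXL2 and TIGD6 were at -1.29 ± 0.06 and -0.96 ± 0.07, and both are uncertain because a retrocopied gene and an overlapping gene can share their reads. Their 25 mM libraries also stood apart, at 51.0 and 31.8 FPKM for RBMXL2 and 11.5 and 8.24 for TIGD6. The standard errors, which rest mostly on the trend across genes, do not show this spread. Among the other rises were DEK (0.97 ± 0.06), the signalosome subunit COPS2 (0.96 ± 0.07), the deubiquitinase USP1 (0.96 ± 0.07) and the apoptosis inhibitor BIRC3 (0.92 ± 0.07).

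Glycolysis and glucose uptake genes fell in 16 of 21 members and rose in 1, SLC16A1, which was named after its value was seen and lost its call with GC correction, at 0.10 ± 0.05 (camera adjusted p = 1.84e-10; adjusted p = 0.561 with an estimated correlation; 13 and 1 after GC correction). GAPDH fell by 0.66 ± 0.02, PKM by 0.60 ± 0.03 and ENO1 by 0.52 ± 0.02. Pentose phosphate and serine pathway genes fell in 9 and rose in 3 of 15 (camera adjusted p = 0.00206; adjusted p = 0.561 with an estimated correlation; 8 and 1 after GC correction). TKT was at -0.80 ± 0.04 and TALDO1 at -0.59 ± 0.06. Ribosomal protein genes, the list that also bears on RNA quality, fell in 23 and rose in 4 of 32 (camera adjusted p = 4.66e-08; adjusted p = 0.561 with an estimated correlation; 22 and 4 after GC correction), with RPL8 at -0.57 ± 0.03. NRF2 targets fell in 12 and rose in 3 of 20 (camera adjusted p = 3.13e-05; adjusted p = 0.561 with an estimated correlation; 14 and 0 after GC correction). HMOX1 was at -0.68 ± 0.08 (-1.55 on log2(FPKM + 1)), FTH1 at -0.49 ± 0.03 and TXNRD1 at 0.00 ± 0.05 (called at -0.15 ± 0.04 with GC correction). SLC7A11 rose by 0.30 ± 0.06 and was at -0.07 ± 0.06 after GC correction. Superoxide, peroxide and glutathione enzymes fell in 11 and rose in 4 of 21 (camera adjusted p = 0.0468; adjusted p = 0.561 with an estimated correlation; 12 and 4 after GC correction). GSTP1 fell by 0.79 ± 0.04, whereas SOD2, the mitochondrial superoxide dismutase, rose by 0.72 ± 0.05, from 58.9 ± 2.53 to 97.5 ± 0.76 FPKM.

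Basal and myoepithelial markers fell in 8 and rose in 3 of 13 (camera adjusted p = 2.45e-05; adjusted p = 0.561 with an estimated correlation; 6 and 2 after GC correction). KRT14 was at -0.79 ± 0.05, KRT5 at -0.62 ± 0.02 and KRT6A at -0.62 ± 0.03. Luminal markers fell in 6 and rose in 1 of 10 (camera adjusted p = 0.0121; adjusted p = 0.561 with an estimated correlation), with KRT18 at -0.49 ± 0.05. SRF and MRTF targets fell in 10 and rose in 2 of 19 (camera adjusted p = 0.000868; adjusted p = 0.561 with an estimated correlation), with ACTB at -0.62 ± 0.02. After GC correction these lists gave camera adjusted p-values of 0.249 and 0.254. MondoA and ChREBP targets had 4 up and 1 down of 9 (camera adjusted p = 0.23), with ARRDC4 at 0.37 ± 0.07 (0.83 on log2(FPKM + 1)) and KLF10 at 0.25 ± 0.07 (0.41 on log2(FPKM + 1), and 0.14 ± 0.06 and not called with GC correction). YAP/TAZ-TEAD targets had 9 up and 2 down of 21 (9 and 1 adjusted over the list alone; camera adjusted p = 0.316, and 0.0151 upward after GC correction; adjusted p = 0.416 with an estimated correlation). CTGF was at 0.06 ± 0.07, CYR61 at -0.01 ± 0.07 and FN1 at -0.03 ± 0.05, and ITGB1 rose by 0.71 ± 0.04. NF-kB genes had 6 up and 1 down of 13 (camera adjusted p = 0.0652), with CXCL8 at 0.86 ± 0.08 (1.55 on log2(FPKM + 1)). After GC correction the counts were 3 up and 1 down for MondoA targets, 9 and 1 for YAP targets, 4 and 0 for NF-kB genes, 2 and 4 for luminal markers and 5 and 7 for SRF targets.

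Stress genes moved both ways at 25 mM. ATF4 targets had 4 up and 7 down of 20 (5 and 7 adjusted over the list alone; camera adjusted p = 0.285; median 0.00, mean -0.08), ATF4 was at 0.07 ± 0.05 and ATF5 fell by 0.39 ± 0.07. Heat shock and chaperone genes had 9 up and 9 down of 20 (adjusted p = 0.864; median -0.09, mean 0.03), with HSP90AA1 at 0.65 ± 0.03, HSPA8 at -0.28 ± 0.03, HSPA1A at -0.35 ± 0.07, DNAJB1 at -0.28 ± 0.06 and HSF1 at -0.58 ± 0.06. With GC correction ATF5 (-0.15 ± 0.07) and HSPA1A (-0.12 ± 0.07) lost their calls, and ATF4 gained one (0.19 ± 0.05). Among mitochondrial genes, quality control had 6 up and 9 down of 18 (10 down adjusted over the list alone; adjusted p = 0.411), complex I 9 and 18 of 37 (adjusted p = 0.11), complexes II to V 9 and 17 of 38 (adjusted p = 0.062, and 0.00182 downward after GC correction; adjusted p = 0.416 with an estimated correlation), the TCA cycle 4 and 9 of 20 (adjusted p = 0.353) and fission and fusion 6 and 6 of 16 (adjusted p = 0.555; median -0.03, mean 0.08). YME1L1 rose by 0.58 ± 0.06 and DNM1L by 0.65 ± 0.07. Cell cycle genes had 9 up and 8 down of 27 (9 and 9 adjusted over the list alone; adjusted p = 0.716), with CDC20 at -0.70 ± 0.05 and PLK1 at -0.58 ± 0.06. The cornification list had 2 up and 7 down of 17 (adjusted p = 0.316). After GC correction the counts up and down were 6 and 4 for ATF4 targets, 6 and 6 for heat shock genes, 4 and 8 for mitochondrial quality control, 6 and 13 for complex I, 5 and 18 for complexes II to V, 4 and 6 for the TCA cycle, 4 and 4 for fission and fusion, 5 and 10 for the cell cycle and 6 and 4 for cornification.

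The remaining lists did not pass camera at 25 mM. Cholesterol synthesis had 8 up and 12 down of 22 (limma camera adjusted p = 0.23), fatty acid synthesis 4 and 6 of 14 (adjusted p = 0.571), peroxisome genes 7 and 9 of 26 (adjusted p = 0.837; median -0.01, mean 0.02) and acid and ion exchange 3 and 7 of 12 (adjusted p = 0.316). The unfolded protein response had 5 up and 8 down of 16 (adjusted p = 0.406), the hypoxia response 7 and 5 of 17 (adjusted p = 0.411), p53 targets 7 and 5 of 18 (8 and 5 adjusted over the list alone; adjusted p = 0.443) and interferon genes 6 and 2 of 16 (adjusted p = 0.543). Integrins and focal adhesion genes had 10 up and 11 down of 23 (adjusted p = 0.944), extracellular matrix genes 4 and 8 of 23 (adjusted p = 0.353), epithelial junctions 8 and 6 of 17 (adjusted p = 0.837) and mesenchymal markers 2 and 4 of 14 (adjusted p = 0.316). For RNA quality, ribosomal protein genes fell as given above, so these lists do not exclude a difference in RNA quality. Histones had 0 called of 6 (adjusted p = 0.919) and nuclear-retained RNAs 7 up and 2 down of 10 (adjusted p = 0.278), and for other cell types fibroblast markers had 1 up and 2 down of 6 (adjusted p = 0.571), leukocyte markers 0 and 2 of 4 (adjusted p = 0.406) and endothelial markers 0 called of 3 (adjusted p = 0.864). With GC correction these lists, ribosomal protein genes aside, did not pass either. Their counts up and down were then 3 and 8 for cholesterol synthesis, 3 and 6 for fatty acid synthesis, 4 and 3 for peroxisome genes, 2 and 5 for acid and ion exchange, 4 and 7 for the unfolded protein response, 7 and 1 for hypoxia, 6 and 2 for p53 targets and 4 and 2 for interferon genes. They were 9 and 9 for integrins, 5 and 3 for matrix genes, 5 and 5 for junctions, 3 and 3 for mesenchymal markers, 1 and 1 for histones, 6 and 3 for nuclear-retained RNAs, 1 and 2 for fibroblast, 0 and 0 for leukocyte and 1 and 0 for endothelial markers.

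At 25 mM 3584 of 12826 genes rose and 3523 fell, 7107 in all, of which 0 rose and 4 fell at least 2-fold on the stabilised scale, against 121 and 22 on log2(FPKM + 1). With GC correction 2690 rose and 2625 fell, 3109 of them called in the same direction in both fits. In simulated data with the observed GC trend and 200 changed genes, 61.0% of the 12622 unchanged genes were called without the correction and 16 of 12498 with it. As for stiffness, the second count was set by the way the trend was added. Without the shallower 400 Pa library the count was 4717. On log2(FPKM + 1) it was 3136 (2259 up and 877 down, or 1687 and 1867 after TMM centring, which moved the median of all genes by -0.102), 687 with GC correction, 0 without either 400 Pa library, 498 and 3 without the deeper and the shallower 25 mM library, and 5142 without either 6 kPa library. The calls of SLC7A11, ATF5, HSPA8, HSPA1A and DNAJB1 ended on log2(FPKM + 1), and that of KLF10 without the shallower 400 Pa library. As for stiffness, the fit on log2(FPKM + 1) takes in the spread of the 6 kPa libraries. Camera on log2(FPKM + 1) gave an adjusted p of 0.0681 for pentose phosphate genes and 0.178 for superoxide, peroxide and glutathione enzymes. It gave 0.304 for SRF targets, 0.195 for luminal and 0.0758 for basal markers. GC correction moved the log2 fold changes of COPS2, USP1, GAPDH, ENO1, RPL8, GSTP1, KRT18, ARRDC4, ITGB1, CXCL8, DNAJB1, HSF1, YME1L1, DNM1L and PLK1 more than 1.5 times toward 0.

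Many genes moved in the same direction in the stiffness and glucose comparisons. Across 12625 genes, which are not independent, the log2 fold changes had a Pearson r of 0.82 and a covariance of 0.069. By contrast, 100 simulations of unchanged groups against the same 400 Pa libraries gave a median r of 0.50 and a median covariance of 0.00231. With GC correction r was 0.63 and the covariance 0.0252 (simulated 0.00211). On log2(FPKM + 1) with GC correction r was 0.47 (simulated median 0.50) and the covariance was 0.0482 (simulated 0.0221). The shared 400 Pa libraries alone set the simulated r near 0.50. An r near that value therefore does not measure how far the likeness exceeds noise. In both comparisons 2617 genes rose, where independent lists would share 947.3. In both, 2393 genes fell, where independent lists would share 894.1. With GC correction 1534 rose and 1410 fell in both, on log2(FPKM + 1) 1483 and 295, and with both settings 194 and 130. The 400 Pa libraries are shared by both comparisons. In opposite directions went 117 genes, or 162 with GC correction, 19 on log2(FPKM + 1) and 26 with both settings. Of the 117, 69 were down with stiffness and up with glucose. TXNIP was such a gene (-1.25 and 0.99), as were SOD2 (-0.72 and 0.72), CXCL8 (-0.22 and 0.86), the pyruvate dehydrogenase kinase PDK4 (-1.15 and 0.56) and ATF3 (-1.19 and 0.29), and the opposite held for the mitotic kinase PLK1 (0.27 and -0.58). ATF3, with 6 and 5 reads in the 60 kPa libraries, was at -2.86 and 0.60 on log2(FPKM + 1), and PDK4 at -1.63 and 0.81. PDK4 was named after its values were seen. All of these kept both directions and passed both tests after GC correction, where CXCL8 was at -0.66 with stiffness, PLK1 at 0.43 with stiffness and PDK4 at 0.29 with glucose. The stiffness call of CXCL8 ended on log2(FPKM + 1) and without either 400 Pa library.

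**Figure D4:**
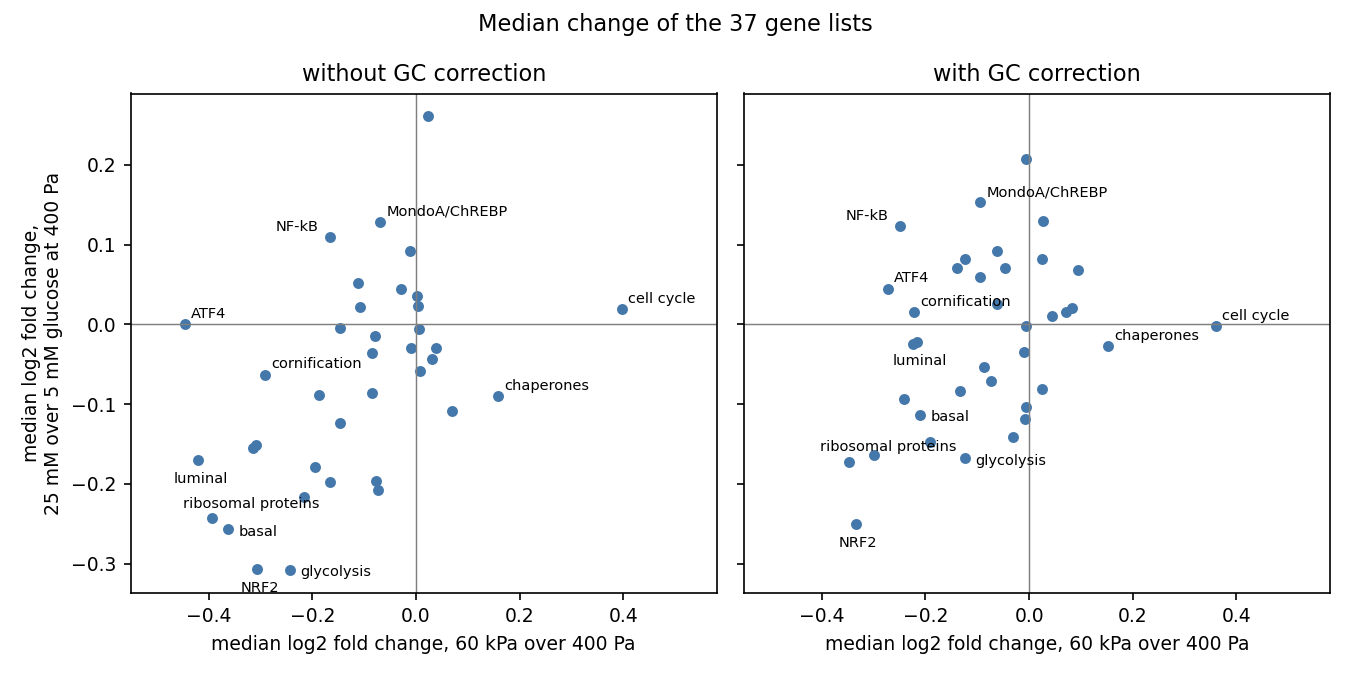
Median log2 fold change of the 37 gene lists for 60 kPa over 400 Pa (horizontal) and 25 mM over 5 mM glucose at 400 Pa (vertical), without (left) and with (right) GC correction; each point is a list and some are named. Cell cycle genes lie at 0.40 and 0.02 without and at 0.36 and 0.00 with the correction, and NF-kB genes lie to the left and above 0 in both panels.

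Set directly against each other, cells on 60 kPa gels and cells at 25 mM glucose on 400 Pa differed in 224 genes in limma's fit on log2(FPKM + 1), of which 55 were higher and 169 lower on 60 kPa, and in 399 and 466 with GC correction. This contrast had little relation to GC content (rho across genes of 0.12). Cell cycle genes were higher on 60 kPa, with 7 of 27 called and a median of 0.44 (camera adjusted p = 8.93e-18; adjusted p = 0.113 with an estimated correlation), and 19 called with GC correction. The cornification list was lower by a median log2 difference of -0.62 (6 of 17 called; adjusted p = 0.0222 with an estimated correlation), ATF4 targets by -0.41 (6 of 19; adjusted p = 0.0244 with an estimated correlation) and NF-kB genes by -0.50 (4 of 14; adjusted p = 0.0222 with an estimated correlation). KRT15 differed by -2.69 (limma adjusted p = 1.12e-05) and ATF3, with 6 and 5 reads in the 60 kPa libraries, by -3.46. Leaving out 1 library moved the 224 calls to 92 (either 400 Pa library at 5 mM), 116 and 113 (the deeper and the shallower 1 kPa library), 709 and 698 (those of 6 kPa), 85 and 50 (those of 60 kPa) and 32 and 37 (those of 25 mM).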

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

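The GC correction, the fits on recovered reads and the alternatives of the direct contrast of 60 kPa with 25 mM were chosen after the data were seen, and the others before. No paired analysis was possible because the columns carry no replicate number. Planned count-based alternatives (edgeR scaling choices, the DESeq2 Wald test, a 3-group count fit, DESeq2 size factors for lists) were not run, and limma-voom on recovered reads stood in for them. Nor was the replicate block.

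The totals of 6589 stiffness calls and 7107 glucose calls stayed within 1.5 times under the filters, the authors' adjusted p, the GC correction and the fits on recovered reads. The genes called were less stable than the totals, since 3085 and 3109 of these calls were kept in the same direction with GC correction. The totals became 2722 and 3136 on log2(FPKM + 1) and 55 and 4 with a 2-fold minimum on the stabilised scale, which shrinks fold changes. On log2(FPKM + 1) 149 rose and 130 fell at least 2-fold with stiffness, and 121 and 22 with glucose. Without a filter, calls were 4 at 1 kPa, 9 at 6 kPa, 1809 at 60 kPa, 8 for 60 against 6 kPa, 9 for 6 against 1 kPa, 2015 at 25 mM and 145 in the direct contrast. A filter of 5 FPKM gave 74 at 6 kPa and 202 for 60 against 6 kPa. TMM centring gave 102 at 6 kPa, 76 for 60 against 6 kPa and 45 for 6 against 1 kPa. GC correction gave 5 at 1 kPa, 260 at 6 kPa, 1288 at 60 kPa, 76 for 60 against 6 kPa, 194 for 6 against 1 kPa, 687 at 25 mM, 865 in the direct contrast and 1058 for the slope. The slope gave 14 calls without the 60 kPa libraries and 983 without those of 400 Pa. List tests past the threshold went from 25 of 74 to 0 with an estimated correlation and 50 with fry. The correlation of both responses went from 0.82 to 0.63 with GC correction, 0.72 on log2(FPKM + 1) and 0.47 with both. Simulations without effects had a median of 0.50 there, a value that the shared 400 Pa libraries set.

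Leaving out 1 library gave between 4365 and 6661 calls for stiffness, 4717 and 7151 for glucose, 0 and 6 at 1 kPa, 2 and 1777 at 6 kPa, 151 and 4503 at 60 kPa, 2 and 4034 for 60 against 6 kPa, 1 and 1725 for 6 against 1 kPa, 0 and 5142 at 25 mM, 32 and 709 in the direct contrast and 868 and 4384 for the slope. A lone library left in a group is assumed to vary like the others. Without 1 of the 6 kPa libraries, the difference within that pair no longer enters the spread shared by the 5 groups. Apart from this, the smaller fits and the changed thresholds, the cause was not tested.

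Of 2173 values of named genes under alternatives 2073 were the same, 91 lost and 7 gained their call, and 2 reversed. Both reversals were SLC7A11 with GC correction, at -0.18 for stiffness and -0.07 for glucose. Of 220 values of gene lists 181 were the same, 36 lost and 3 gained their call, and 0 reversed. The shallower 6 kPa library held 1.97 M exon reads, the fewest of all, and calls at 6 kPa numbered 89 without it and 1777 without the deeper one.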

Other observations

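The tests of GC-dependent yield and of stiffness as a whole cause for the library split, and of GC-dependent yield for the cornification list, were chosen after their results were seen, the others before.

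In all, 61 genes, those named above among them, changed in opposite directions with stiffness and glucose under both settings of GC correction. Those named here were chosen after their values were seen, and on log2(FPKM + 1) the stiffness calls of CLDN1, DSG3, TUBB4B and MYBL2 and the glucose call of TUBB ended. CLDN1, a tight junction protein, was at -0.33 on 60 kPa and 0.55 at 25 mM, and DSG3, a desmosomal cadherin, at -0.28 and 0.52. TSC22D3, a glucocorticoid-induced gene, was at -1.17 and 0.15. The tubulins TUBB and TUBB4B were at 0.36 and -0.30 and at 0.16 and -0.60, and MYBL2, a transcription factor of cycling cells, at 0.14 and -0.62.

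The libraries split along GC content, with the 60 kPa, the 25 mM and 1 of the 6 kPa libraries on 1 side. GC-dependent yield of the libraries would predict such a split between libraries of 1 treatment, and the 6 kPa libraries differed along GC with a rho across genes of -0.603. That value restates part of the split, so it is not a separate test of this explanation. Stiffness as the whole cause is argued against by the 25 mM libraries on 400 Pa gels, whose highest rho was -0.642. A wrong label on a 6 kPa library is argued against by their GC-corrected positions between 400 Pa (0) and 60 kPa (1), 0.606 and 0.604 over 108 genes. Of these genes 96 were falls, and over the 12 rises the positions were 0.328 and 0.509. Pearson correlations without GC correction went the other way. The deeper 6 kPa library had 0.978 with the deeper 400 Pa library, and the shallower had 0.967 and 0.971 with those of 60 kPa. The 6 kPa libraries had 0.955 with each other. These correlations include the GC split, so they cannot decide on the label. Over the 108 genes the positions were 0.168 and 0.221 at 1 kPa, 0.978 and 1.022 at 60 kPa and 0.268 and 0.289 at 25 mM. Both 6 kPa libraries thus lay apart from every other group, which argues against a wrong label. Over the 12 rises other groups overlapped them, with 0.323 in the shallower 1 kPa library, so the rises alone do not exclude it. Whether the yield arose in library preparation or in the cells stays open, since no table separates these.

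The cornification list fell on 60 kPa gels. GC-dependent yield alone is argued against by the contrast with the 25 mM libraries, which share the sign of the GC trend, where the list's median was -0.619. Thinning to equal depth left a median ratio of 1.016 of the change over 12 members, and all 12 stayed past the test. The calls thus did not hinge on the extra reads. Random thinning keeps expected ratios, however, so it cannot decide whether differences that came with depth caused the fall. After GC correction the fallen members kept a median of 0.779 of their change, and 10 of 13 stayed past the test. Stiffness itself stays open as the cause, since each group has 2 libraries and no batch is given.

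The stiffness and glucose responses resembled each other. In the deposited values the covariance was 28.5 times the highest simulated value. This argues against independent noise in the shared 400 Pa libraries as the whole cause. The simulations drew noise gene by gene, so they cannot decide on a shift common to both 400 Pa libraries. On log2(FPKM + 1) with GC correction the evidence against independent noise was weaker. The covariance there was 0.0482 against 0.0254 in the highest simulation. The r of 0.471 does not bear on this. Shared 400 Pa libraries alone set the simulated r (median 0.496), and effects particular to 1 treatment lower r. GC-dependent yield could account for part, since the covariance after GC correction was 0.365 of that without it. What remains in the deposited values, a covariance of 0.0252 against 0.00223 in the highest simulation, stays open between a shared response of the cells and other differences between libraries.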
